A study of Mus musculus with 35 samples.

How the data were processed

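RNA-seq counts were analysed from 35 libraries of mouse LT-HSCs in 6 genotype groups of 4 to 8 libraries. Per the labels' protocols, total RNA came from 1000 sorted cells per library, was isolated with a kit for very small samples, and entered a SMARTer low-input library preparation. The deposited values were raw counts per Entrez gene, with 19139 entries per library, of which 19138 were genes and 1 was a part of Ezh2 counted on its own. Per the submitters' processing notes, STAR and the mouse genome build mm9 were used. The version of the aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. Without strand, counts of a gene and an overlapping or antisense partner cannot be told apart. The part of Ezh2 made up at most 0.000935% of a library's counts and was kept out of library sizes and tests. Gene symbols came from a reference of another build, used for names only, and matched 19075 of the 19138 genes, leaving 63 unmatched. No coordinates are given, because the build of the reference differs from that of the counts. Counts of 6 sets of gene copies were identical in every library, among them Hba-a1 with Hba-a2 and Hbb-b2 with Hbb-bt, and such copies are uncertain.

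Groups, batch, sex and replicate numbers came from the labels. No label says which animal a library came from, so p-values measure the spread between these libraries. Total counts per library were 13.6 to 48.6 M (mega, median 24.9 M), and 13584 to 15162 genes had counts. Confidence intervals of shares are Wilson intervals at 95%, and limits for a count of 0 use 3 counts. Both cover counting error only, because the reads carry no molecular identifiers.

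The main test was the quasi-likelihood test of edgeR 4.0.16 with R 4.3.3, fitted to all 35 libraries with terms for group, batch and sex, so that all groups shared 1 estimate of the spread. TMM normalisation gave factors from 0.937 to 1.062. The low-count filter of edgeR left 14945 genes and removed 4193, of which 41 had no count in any library. The common biological coefficient of variation was 0.554 with 27 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Log2 changes came from this fit, and their SE was the absolute log2 change divided by the square root of the F statistic. A prior count of 2 was used for the log2 CPM of the list tests and of the check of replicate numbers, not for the log2 changes. Group means of CPM used TMM-normalised library sizes, and counts of libraries beyond another group, list levels per library and values of single libraries used total counts. Levels of a list are means of log2(CPM + 1) over its genes. Values of this kind were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over 4 tests. These tests had no terms for batch or sex, and of the gene lists only the interferon-stimulated genes were compared in this way.

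A set of 24 gene lists was tested in each comparison with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. The lists were written from general knowledge, and 646 of 673 entries, including a list of sex-linked genes used as a label check, matched a gene in the counts. Groups, the edgeR and list tests, the overlap of Ezh2-null calls, covariates, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The exact permutation tests were not among the tests listed then. Nor were the overlap of JAK2-VF calls and the test, as sets, of genes called for Ezh2 loss with JAK2-VF. The rule took Ezh2, Ezh1 and Jak2, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 (leaving out predicted genes, RIKEN clones, Y-linked genes and Xist), up to 4 called members of each list with the smallest adjusted p, the 3 smallest p-values in a direction where fewer than 5 genes passed, and the 5 smallest adjusted p-values for differences of effects. The text names a part of these, picked after their values were seen, and some genes are not reported here. Egr1, Lgals1 in the JAK2-VF comparisons, Osm and Mycn in cells without Ezh2, and Hbb-bt in Ezh2-null against control cells lay outside the rule and were chosen after their values were seen.

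The alternatives were size factors of DESeq2 1.42.0, no low-count filter, the DESeq2 Wald test, limma-voom with quality weights, no term for sex, the replicate number as a block, a fit of the compared groups only, each batch alone, females alone and leaving out each library in turn. A fit without the 2 doubted libraries, those labelled Ezh2-heterozygous batch 1 replicates 1 (Xist) and 3 (no exon counts of Ezh2), was added after seeing the data. The other libraries labelled heterozygous whose exon part of Ezh2 showed no loss stayed in that fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

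The test was checked on simulated counts for 14714 genes with known changes. Of genes above 8 CPM changed 4-fold, 94.7% were recovered for Ezh2-null against control and 97.7% for JAK2-VF Ezh2-null against JAK2-VF, and of those changed 2-fold 32.7% and 84.8%. No recovered gene had the wrong direction. Among unchanged genes, 10 were called in the simulation of JAK2-VF Ezh2-null against JAK2-VF and 9 in that of JAK2-VF Ezh2-heterozygous against JAK2-VF. Between 1 and 4 were called in the other comparisons. What share of all simulated calls these made up was not counted. Of 200 unchanged lists in the simulation of JAK2-VF Ezh2-null against JAK2-VF, 2 had a p under 0.05 by camera with the preset correlation, 4 with an estimated correlation and 11 by fry. Simulated genes were drawn independently, with no batch or sex effect. In the real data the estimated correlation was 0.221 for the interferon list and 0.492 for the proliferation list. The simulation therefore cannot show how often correlated lists are called without a change.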

Results

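RNA was measured in long-term haematopoietic stem cells (LT-HSCs), the rare self-renewing cells that give rise to all blood lineages, from mice of 6 genotypes. All mice carried SclCre, a Cre recombinase expressed in blood stem cells, and Ezh2 was intact, lost from 1 allele or lost from both, with or without JAK2-V617F, the activating kinase mutation of myeloproliferative neoplasms (here JAK2-VF). The groups held 4 control, 7 Ezh2-heterozygous, 4 Ezh2-null, 6 JAK2-VF, 8 JAK2-VF Ezh2-heterozygous and 6 JAK2-VF Ezh2-null libraries, each from 1000 sorted cells. Of the 35 libraries, 20 came from females and 15 from males, and 14 belonged to batch 1 and 21 to batch 2. All 4 controls were female, and the 6 JAK2-VF libraries were 2 females in batch 1 and 4 males in batch 2. The Ezh2-null libraries were 1 female and 3 males, and the JAK2-VF Ezh2-null libraries 5 females and 1 male. Sex was thus unbalanced in both comparisons of Ezh2-null libraries, in opposite directions, and the fit held a single shared term for it. Total counts per library ran from 13.6 to 48.6 M (mega, median 24.9 M), with batch medians of 22.58 and 32.34 M. The comparisons ask what each change did to stem-cell RNA alone, and whether Ezh2 loss acted differently in JAK2-VF cells. Levels as CPM, counts scaled to a library total of 1 M, are given with the SD over a group's libraries, and log2 changes with their SE.

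Ezh2, the catalytic subunit of the gene-silencing complex PRC2, was measured both as a whole gene and as a separate part of the gene whose length, 178 bases, equals that of exons 16 and 17 together. The part was matched to these exons by its length alone, in a transcript of another genome build, so that it is the deleted part of the gene is not certain. The part held 7.28 ± 1.11 of every 100 Ezh2 counts in control libraries (SD, n = 4) and 7.62 ± 0.97 in JAK2-VF libraries (n = 6). In Ezh2-null libraries it held 0.12 ± 0.24 (n = 4; exact two-sided permutation p = 0.0286 against control, the smallest these group sizes allow, 0.0571 adjusted over 4 tests). JAK2-VF Ezh2-null libraries had 0 of 5046 counts in it (n = 6; exact permutation p = 0.00216 against JAK2-VF, adjusted 0.00866), which allowed a share of up to 0.213 to 0.634% in single libraries. One of the 4 Ezh2-null libraries, batch 2 replicate 2, kept 3 of 627 counts there, a share of 0.478% (Wilson 95% interval 0.163 to 1.397%). Libraries labelled heterozygous held 4.61 ± 3.63 of every 100 counts (n = 7; exact permutation p = 0.2, adjusted 0.229), and with JAK2-VF 6.69 ± 1.57 (n = 8; exact permutation p = 0.229, adjusted 0.229). Neither difference passed, although 5 of the 7 libraries labelled heterozygous lay below every control and 3 of the 8 with JAK2-VF below every JAK2-VF library. In batch 2 all 4 libraries labelled Ezh2-heterozygous, at 1.738 to 5.797%, lay below both controls, at 6.02 and 8.718%. In the libraries labelled Ezh2-heterozygous batch 1 replicates 1 and 2 its share was 9.497% (Wilson 95% interval 7.746 to 11.595%) and 8.657% (7.072 to 10.556%). The batch 1 controls were at 7.037 and 7.343%, so the part showed no loss in these 2 libraries. With JAK2-VF, 5 of the 8 libraries labelled heterozygous, at 6.511 to 8.495%, lay within the 6.342 to 9.272% of the JAK2-VF libraries, and the part showed no loss in these either. An unchanged share alone does not show a label to be wrong. Whole-gene Ezh2 lay below every JAK2-VF library in 6 of the 8 libraries labelled heterozygous with JAK2-VF. Without JAK2-VF it lay below every control in 1 of the 7.

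In 2 libraries labelled Ezh2-heterozygous values went against a label. The library labelled Ezh2-heterozygous batch 1 replicate 3 had 0 of 831 Ezh2 counts in the exon part, which allowed at most 0.361%, as in libraries with both alleles lost. The library labelled Ezh2-heterozygous batch 1 replicate 1 and male held 394.15 CPM of Xist, the X-inactivation RNA, against at most 14.75 CPM in the other males and 581.73 to 1432.73 CPM in the females. All libraries entered the main fit under their labels. Values given for either group labelled heterozygous rest in part on libraries in which the part showed no loss. Those of the Ezh2-heterozygous group also rest on the library without counts in the part.

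**Figure D1:**
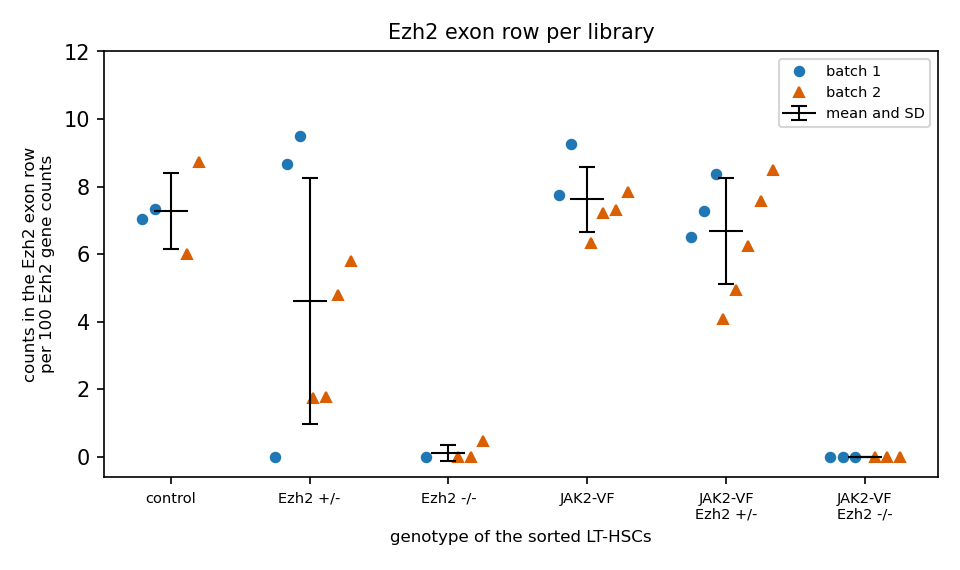
Counts in the exon part of Ezh2 per 100 counts of the whole gene (y axis) for each library, by genotype group (x axis), with circles for batch 1, triangles for batch 2 and the group mean and SD. Controls averaged 7.28 and JAK2-VF libraries 7.62, the 6 JAK2-VF Ezh2-null libraries were all at 0, and 1 of the 7 libraries labelled Ezh2-heterozygous was at 0 too.

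The whole-gene level of Ezh2 fell from 75.37 ± 21.4 CPM in JAK2-VF cells (n = 6) to 26.86 ± 7.66 in JAK2-VF Ezh2-null cells (n = 6), a log2 change of -1.5 ± 0.21 (edgeR adjusted p = 8.22e-05). Without JAK2-VF it was 45.07 ± 13.8 CPM in controls and 22.93 ± 3.86 in Ezh2-null cells, a change that missed the threshold over all genes (log2 -0.95 ± 0.26, edgeR adjusted p = 0.453). Libraries labelled heterozygous held 36.82 ± 8.72 CPM, or 48.24 ± 13.9 with JAK2-VF, and neither comparison passed (edgeR adjusted p = 1 for both). Jak2 (Entrez 16452) was 54.92 ± 6.9 CPM in controls and 67.35 ± 17.2 in JAK2-VF cells (log2 0.39 ± 0.17, edgeR adjusted p = 0.223). Whether its counts include RNA of the mutant cannot be told. Jak2 rose in JAK2-VF Ezh2-null cells, to 88.59 ± 31.7 CPM, against Ezh2-null cells (log2 0.68 ± 0.17, edgeR adjusted p = 0.0159). That call was lost without Ezh2-null batch 1 replicate 1 or batch 2 replicate 1, where the adjusted p reached 0.0998. Levels differed by batch: JAK2-VF Ezh2-null libraries held 106 to 137 CPM in batch 1 and 55.2 to 68.3 CPM in batch 2. Ezh2-null libraries held 51.3 CPM in batch 1 (1 library) and 37.6 to 55.6 CPM in batch 2.

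JAK2-VF stem cells held more RNA of dividing cells and less RNA of many stem-cell genes than control stem cells. Of 52 proliferation genes, 36 rose and 0 fell (50 rose when adjusted over the list alone), with a median log2 change of 1.65. The mitotic kinase gene Cdk1 (Entrez 12534) went from 27.14 ± 8.38 CPM in controls (n = 4) to 101.3 ± 32.7 in JAK2-VF cells (n = 6), a log2 change of 1.83 ± 0.29 (edgeR adjusted p = 0.000245), and lay above every control in 6 of 6 libraries. Of 45 HSC signature genes, 16 fell and only Egr1 rose (23 and 1 when adjusted over the list alone), with a median of -0.47. Mllt3, a regulator of stem-cell self-renewal, fell from 407.2 ± 54.7 to 169.5 ± 33 CPM, a log2 change of -1.30 ± 0.16 (edgeR adjusted p = 5.91e-06), below every control in 6 of 6 libraries.

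In all, 631 of 14945 genes changed between JAK2-VF and control cells, 358 of them higher and 273 lower. Other division genes with large rises were Bub1b of the spindle checkpoint (log2 2.04 ± 0.33), the condensin subunit gene Ncapg (2.77 ± 0.47), the cohesin acetyltransferase gene Esco2 (2.65 ± 0.47), the mitotic kinase gene Pbk (2.67 ± 0.32) and the cell-cycle transcription factor gene E2f8 (2.89 ± 0.60), with edgeR adjusted p of at most 0.00351. The thymidylate synthase gene Tyms rose by 1.40 ± 0.22 (edgeR adjusted p = 0.000245). Both list shifts held with an estimated correlation (adjusted p = 0.0115 for proliferation and 0.00348 for the HSC signature). Among signature genes, the growth suppressor gene Ndn fell from 117.5 ± 23.4 to 50.44 ± 14.3 CPM (log2 -1.40 ± 0.14, edgeR adjusted p = 2.28e-07). The transcription factor gene Hoxa9 fell by 0.86 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00145). Runx1t1, a transcriptional co-repressor gene, fell by 2.86 ± 0.38 (edgeR adjusted p = 2.3e-05). Ramp2, the adrenomedullin receptor partner, went from 17.9 ± 11.1 to 0.356 ± 0.461 CPM, and Meg3, an imprinted long noncoding RNA, from 24.79 ± 9.89 to 0.426 ± 0.433 CPM (edgeR adjusted p = 0.000296 and 0.000233).

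Smaller lists moved with them. Of 18 Hox A and B cluster genes, 3 fell (Hoxa9, Hoxa5 and Hoxb6; 5 when adjusted over the list alone), and of 15 fetal and oncofetal genes 2 fell, Ndn and the cell-cycle inhibitor gene Cdkn1c, both also in the HSC list (6 when adjusted over the list alone). Both list shifts held with an estimated correlation (adjusted p = 0.00992 and 0.00348). Hoxa5 lost its call without any 1 of 4 libraries and Hoxb6 without any 1 of 9 (highest edgeR adjusted p = 0.142 and 0.117). Of 29 immediate-early genes 6 rose (9 when adjusted over the list alone), including Zfp36, which encodes an mRNA decay factor (log2 1.31 ± 0.29, edgeR adjusted p = 0.0065), but the list call was lost, with adjusted p = 0.322 with an estimated correlation. Of 27 JAK-STAT target genes only Socs2, a feedback inhibitor of cytokine signalling, rose and only Ccnd1 fell (5 rose and 4 fell when adjusted over the list alone; adjusted p = 0.95 with an estimated correlation). Socs2 (Entrez 216233) went from 41.08 ± 13.3 to 140.1 ± 25.2 CPM, a log2 change of 1.61 ± 0.25 (edgeR adjusted p = 0.000168), in 6 of 6 libraries above every control. Ccnd1 lost its call without control batch 1 replicate 1 or JAK2-VF batch 1 replicate 1 (edgeR adjusted p up to 0.0583). Gata1, the erythroid and megakaryocyte transcription factor gene, rose by 2.18 ± 0.50, and Csf2rb, the shared receptor chain for interleukin-3 and GM-CSF, by 1.65 ± 0.26 on the log2 scale (edgeR adjusted p = 0.00854 and 0.000245).

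The genes given here with a log2 change or CPM and past the threshold lay beyond every control in 6 of 6 libraries, except Hoxa9 (3 of 6, and below the control mean in 6). Within batch 1 alone 83 genes passed and within batch 2 alone 38, with 73 and 31 of these among the 631, and in females alone 411. Leaving out control batch 1 replicate 1, JAK2-VF batch 1 replicate 1 or JAK2-VF batch 1 replicate 2 left 282, 314 and 399 genes, and DESeq2 called 1003.

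**Figure D2:**
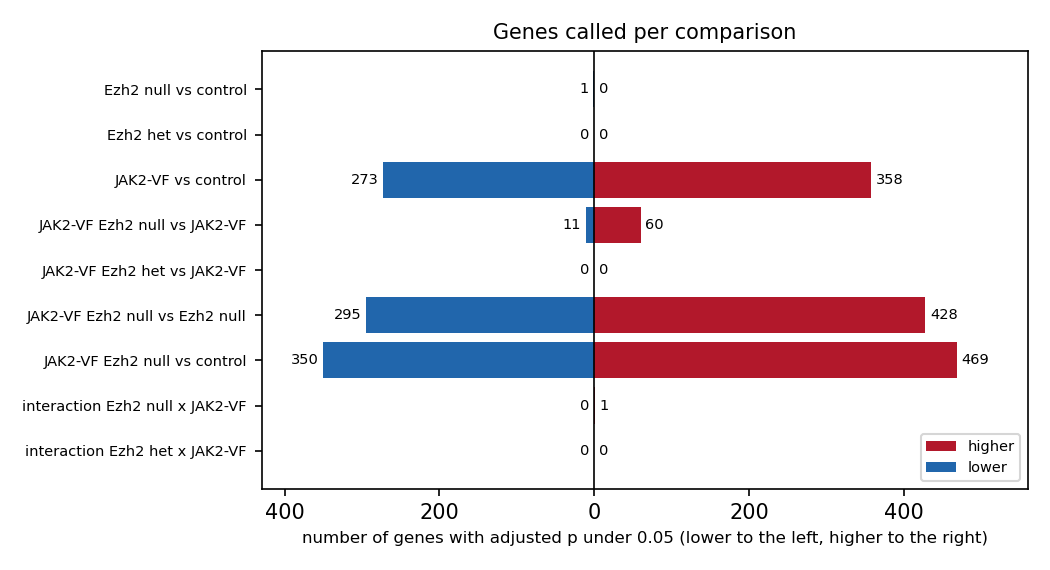
Number of genes with an edgeR adjusted p under 0.05 (x axis) in each comparison (y axis), with bars for higher genes to the right of 0 and for lower genes to the left. JAK2-VF against control gave 631 genes and JAK2-VF Ezh2-null against Ezh2-null 723, and Ezh2 loss gave 71 with JAK2-VF and 1 without it.

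JAK2-VF stem cells without Ezh2 held more RNA of interferon-stimulated genes, and of a small set of other genes, than JAK2-VF cells with Ezh2. Of 50 interferon-stimulated genes, 14 rose and 0 fell (36 rose when adjusted over the list alone), with a median log2 change of 0.61 and 49 positive values. The guanylate-binding GTPase gene Gbp7 (Entrez 229900) went from 421.1 ± 54 CPM in JAK2-VF cells (n = 6) to 849.9 ± 185 in JAK2-VF Ezh2-null cells (n = 6), and its relative Gbp3 from 90.99 ± 15.8 to 215.4 ± 50.2. These were log2 changes of 0.90 ± 0.11 and 1.20 ± 0.16 (edgeR adjusted p = 3e-05 for both), with 6 of 6 libraries above every JAK2-VF library. Mab21l2 (Entrez 23937), a gene of eye development, went from 2.54 ± 2.55 to 70.74 ± 29.9 CPM, a log2 change of 4.89 ± 0.88 (edgeR adjusted p = 0.00362).

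In all, 71 genes changed, 60 higher and 11 lower. Ifit1, which encodes a sensor of viral RNA, rose by 1.64 ± 0.29 on the log2 scale and Zbp1, a nucleic-acid sensor gene, by 1.5 ± 0.28 (edgeR adjusted p = 0.00248 and 0.00377). The interferon list held with an estimated correlation (adjusted p = 0.000317). The mean log2 level over the list was 5.95 ± 0.13 in JAK2-VF and 6.71 ± 0.22 in JAK2-VF Ezh2-null libraries (exact two-sided permutation p = 0.00216, adjusted over 4 tests 0.00866), and differed by 0.81 within batch 1 and 0.71 within batch 2. Markers of neutrophils and monocytes averaged 5.27 ± 0.75 and 4.85 ± 0.915 on the same scale, and 0 of 37 changed by edgeR, 0 also when adjusted over the list alone. Of 15 fetal and oncofetal genes, Ndn and Lin28b rose and Igf2 fell (6 rose and 1 fell when adjusted over the list alone), with a median of 0.62, also with Igf2 at its bound, and adjusted p = 0.00187 with an estimated correlation. Lin28b (Entrez 380669), an RNA-binding protein gene of fetal stem cells, had 2 counts over the JAK2-VF libraries and 1262 over the JAK2-VF Ezh2-null libraries, a ratio of 602 (exact interval 166 to 4980, counting error only; edgeR adjusted p = 0.00839). Its call was lost without JAK2-VF Ezh2-null batch 2 replicate 2 (edgeR adjusted p = 0.0799). Igf2 (Entrez 16002), a fetal growth factor gene, had 0 counts in JAK2-VF Ezh2-null libraries and 119 in JAK2-VF libraries, at least 41.5-fold lower against a floor of 3 counts over the group.

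Hbb-bt (Entrez 101488143), an adult beta-globin gene with counts identical to those of its copy Hbb-b2, rose from 24.29 ± 9.26 to 234.3 ± 110 CPM, a log2 change of 3.47 ± 0.46 (edgeR adjusted p = 5.79e-05). Counts of these copies could not be told apart, and the rise cannot be assigned to one of them. Ndn rose from 50.44 ± 14.3 to 88.98 ± 21.7 CPM (log2 0.97 ± 0.13, edgeR adjusted p = 3e-05) and Ramp2 from 0.356 ± 0.461 to 6.59 ± 6.96 CPM (edgeR adjusted p = 0.00819). Of the 45 HSC signature genes 4 rose, Ndn, Ramp2, Ifitm1 and Mycn (9 rose and 4 fell when adjusted over the list alone), and the list as a whole was not called, with adjusted p = 0.611 with an estimated correlation. Serpina3f, a serine protease inhibitor gene, rose by 2.47 ± 0.41 and Bex2 by 2.01 ± 0.34 on the log2 scale (edgeR adjusted p = 0.000799 and 0.00118). The homeodomain transcription factor gene Cux1 fell from 516.1 ± 39.6 to 380 ± 15.7 CPM, a log2 change of -0.45 ± 0.08 (edgeR adjusted p = 0.00159). Vldlr, a lipoprotein receptor gene, fell by 2.04 ± 0.40 (edgeR adjusted p = 0.00653). Of 29 immediate-early and dissociation stress genes, which also respond to cell handling, 1 had a positive value, with a median of -0.39 and 0 called by edgeR, 0 also when adjusted over the list alone. That list was called at the preset correlation (adjusted p = 4.81e-07) and lost with adjusted p = 0.444 with an estimated correlation. None of 52 proliferation genes and none of 16 developmental regulators known as PRC2 targets changed, which was 0 by edgeR for both lists, over all genes and adjusted over the list alone. Only these 16 of the 56 regulators matched in the counts passed the low-count filter, so most of that list was not tested.

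Of the genes given here with a log2 change, Ndn and Vldlr lay beyond every JAK2-VF library in 5 of 6 libraries and the others in 6 of 6. Within batch 1 alone 1 gene passed and within batch 2 alone 22, in females alone 8 and in a fit of the compared groups alone 22, while DESeq2 called 193 and limma-voom 107. Without JAK2-VF batch 1 replicate 1 the count was 38, and Ifitm1 and Mycn lost their calls without any 1 of 7 and 8 of the 12 libraries (highest edgeR adjusted p = 0.149 and 0.143).

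**Figure D3:**
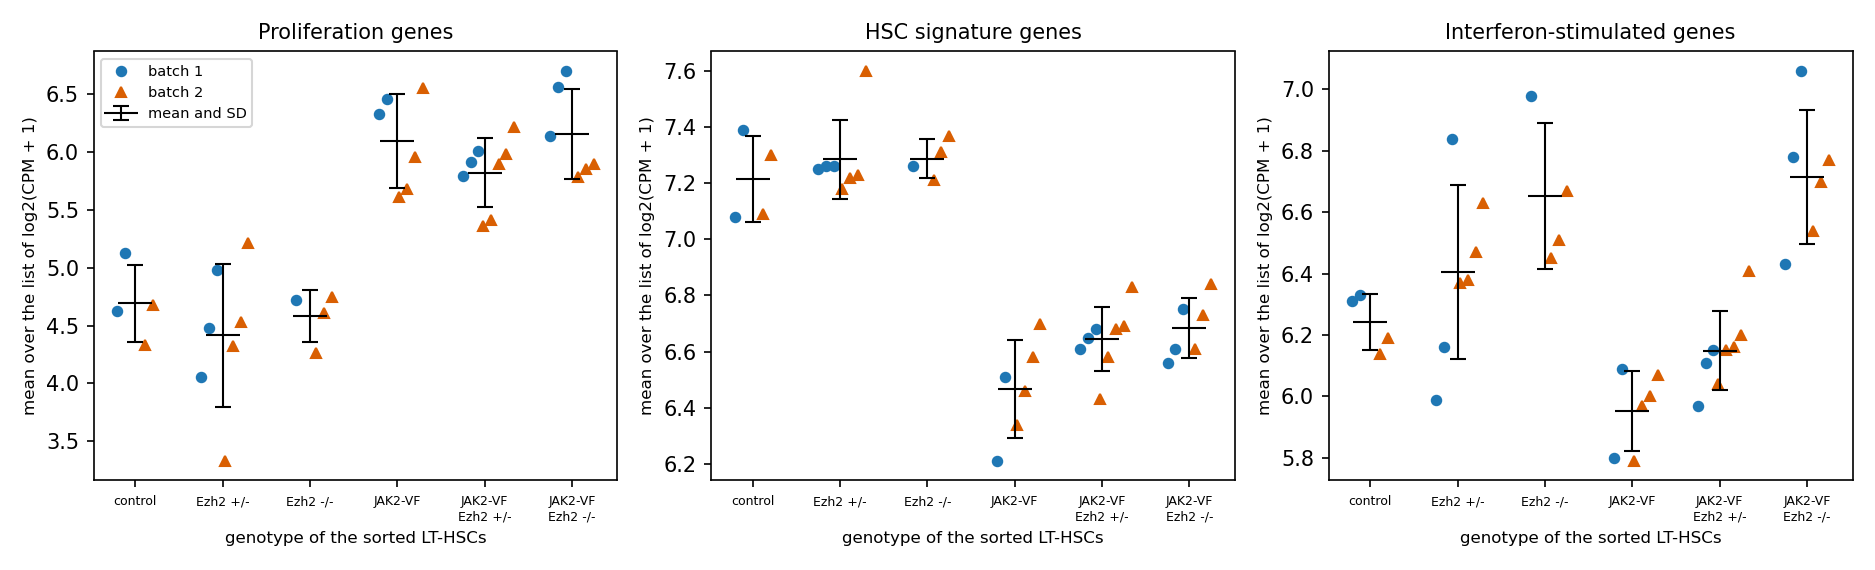
Mean of log2(CPM + 1) over the proliferation, HSC signature and interferon-stimulated lists (y axes) for each library, by genotype group (x axis), with circles for batch 1, triangles for batch 2 and the group mean and SD. JAK2-VF Ezh2-null libraries averaged 6.71 for interferon-stimulated genes against 5.95 in JAK2-VF, and proliferation averaged 6.1 in JAK2-VF against 4.69 in controls.

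In stem cells without JAK2-VF, loss of both Ezh2 alleles changed a single gene past the threshold. Coro2a (Entrez 107684), an actin-binding coronin gene, fell from 184.1 ± 54.5 CPM in controls (n = 4) to 75.62 ± 30.5 in Ezh2-null cells (n = 4), a log2 change of -1.21 ± 0.22 (edgeR adjusted p = 0.0462), below every control in 4 of 4 libraries. Next in order was Cd69, an early activation marker gene, at 33.42 ± 18.4 and 117 ± 43.4 CPM, which did not pass the threshold (edgeR adjusted p = 0.272). Exosc1, of the RNA exosome, and Gas2l3, of the cytoskeleton, had log2 values of -0.66 ± 0.15 and -0.88 ± 0.20 and did not pass either (edgeR adjusted p = 0.272 for both).

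Interferon-stimulated genes had a median log2 value of 0.48, positive for 45 of 50, with 0 called over all genes by edgeR and 4 when adjusted over the list alone. The list call with the preset correlation (adjusted p = 3.12e-20) was lost, with adjusted p = 0.0506 with an estimated correlation. Their mean log2 level was 6.24 ± 0.09 in controls and 6.65 ± 0.24 in Ezh2-null libraries, higher in 4 of 4 than in every control (exact two-sided permutation p = 0.0286, the smallest these group sizes allow, adjusted 0.0381). This permutation test was run on no other list. It had no term for sex, while all 4 controls were female and 3 of the 4 Ezh2-null libraries male. It therefore does not restore the list call. Ifi27, a member of that list, was at 126.5 ± 13.9 and 214.2 ± 46.8 CPM without passing (edgeR adjusted p = 0.415). Neutrophil and monocyte genes had a median of -1.18 and 0 called by edgeR (1 higher and 2 lower when adjusted over the list alone). Their list call at the preset correlation (adjusted p = 2.1e-06) was lost with adjusted p = 0.336 with an estimated correlation. Immediate-early genes had a median of 0.48, NF-kB and inflammatory genes 0.50 and megakaryocyte genes 0.24, with 0 called in each. These lists were called at the preset correlation (adjusted p = 1.07e-06, 0.000568 and 0.049) and lost with an estimated correlation (adjusted p = 0.336, 0.0528 and 0.517). An unadjusted p under 0.05 was found for 891 genes, where 747 would be expected by chance.

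Coro2a lost its call without any 1 of 5 of the 8 libraries (control batch 1 replicate 1 and batch 2 replicate 4, and Ezh2-null batch 1 replicate 1, batch 2 replicate 2 and batch 2 replicate 3; edgeR adjusted p up to 0.567). No gene passed within batch 1 or batch 2 alone with edgeR, or with limma-voom, and DESeq2 called 97.

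The effects of Ezh2 loss with and without JAK2-VF come from separate libraries, but from a single fit with shared terms for batch and sex. With 0 genes higher and 1 lower called without JAK2-VF, too few were called for a test of shared genes. The log2 changes had a Pearson correlation of 0.004 across the 10183 genes with a mean log2 CPM of at least 3 and of -0.152 across all 14945 tested genes, which are not independent replicates. Of the 60 genes higher in JAK2-VF Ezh2-null than in JAK2-VF cells, 37 were also higher in Ezh2-null than in control cells, with a median log2 value of 0.32. As a set they moved up there (fry p = 0.0146, and camera p = 0.00949 with an estimated correlation, both unadjusted). The set holds 14 interferon-stimulated genes, a list with positive values for 45 of 50 genes in Ezh2-null against control cells. Whether the other genes of the set moved was not tested, so the shift may repeat that of the interferon list. Of the 11 lower genes 6 were also lower there and 5 higher, with a median of -0.06, and they did not move as a set (fry p = 0.0504, and camera p = 0.17 with an estimated correlation).

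In cells without Ezh2, JAK2-VF again went with more proliferation RNA and less stem-cell RNA. Of 52 proliferation genes 40 rose and 0 fell (48 rose when adjusted over the list alone), with a median log2 change of 1.63, and of 45 HSC signature genes 20 fell and 2 rose, Ifitm1 and Mycn (23 and 4 when adjusted over the list alone). Socs2 went from 28.76 ± 7.44 CPM in Ezh2-null cells (n = 4) to 228.5 ± 67.9 in JAK2-VF Ezh2-null cells (n = 6), a log2 change of 3.16 ± 0.26 (edgeR adjusted p = 6.16e-10). Cish, another STAT-induced inhibitor of cytokine signalling, went from 126 ± 36.9 to 459.2 ± 199 CPM, a log2 change of 2.01 ± 0.27 (edgeR adjusted p = 1.12e-05). For both genes 6 of 6 libraries lay above every Ezh2-null library.

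In all, 723 genes changed, 428 higher and 295 lower, and both lists held with an estimated correlation (adjusted p = 0.0326 for proliferation and 0.00514 for the HSC signature). Bub1b rose by 2.47 ± 0.34, Cdk1 by 1.85 ± 0.29 and the cyclin gene Ccna2 by 1.98 ± 0.31 on the log2 scale, with edgeR adjusted p of at most 0.000111. Trpc6, a cation channel gene, fell by 1.30 ± 0.16 and Mllt3 by 1.19 ± 0.15, with edgeR adjusted p of at most 5.25e-06. Of 27 JAK-STAT target genes 4 rose, Socs2, Cish, the survival kinase gene Pim2 and the cytokine gene Osm, and Bcl6, a transcriptional repressor gene, fell (5 and 3 when adjusted over the list alone), and the list as a whole was not called (median -0.09, adjusted p = 0.709 with an estimated correlation). Pim2 lost its call without Ezh2-null batch 2 replicate 1 or 3 and Bcl6 without Ezh2-null batch 2 replicate 1 or JAK2-VF Ezh2-null batch 2 replicate 2 (edgeR adjusted p up to 0.0811 and 0.131). For Pim2, 5 of 6 JAK2-VF Ezh2-null libraries lay above every Ezh2-null library and 1 lay below every one. Csf2rb rose by 2.28 ± 0.26 (edgeR adjusted p = 1.1e-06), and the cytochrome oxidase subunit gene Cox4i2 by 3.49 ± 0.43 (edgeR adjusted p = 2.88e-06), and the adhesion molecule gene Ncam2 by 3.42 ± 0.46 (edgeR adjusted p = 1.01e-05). Meg3 fell from 44.8 ± 11.3 to 0.682 ± 0.914 CPM, and Cyp26b1, which encodes a retinoic acid-degrading enzyme, from 37.29 ± 17.4 to 0.433 ± 0.494 CPM (edgeR adjusted p = 1.12e-05 and 2.21e-05).

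Of 10 MHC class II genes 4 fell, H2-DMa, H2-DMb1, H2-Ab1 and H2-Aa (6 when adjusted over the list alone), with adjusted p = 3.7e-06 at the preset correlation and 0.0684 with an estimated correlation. Each of these 4 lost its call without at least 2 of the 10 libraries (highest edgeR adjusted p = 0.0705, 0.0973, 0.118 and 0.109). For H2-Aa, 5 of 6 JAK2-VF Ezh2-null libraries lay below every Ezh2-null library and 1 lay above every one. Of 18 Hox genes 2 fell, Hoxa5 and Hoxa3 (3 when adjusted over the list alone), with adjusted p = 0.000912 at the preset correlation and 0.0684 with an estimated correlation. Hoxa3 lost its call without any 1 of 8 libraries (edgeR adjusted p up to 0.23). Of 37 neutrophil and monocyte genes 3 rose, Csf2rb and the neutrophil protease genes Mmp8 and Mmp9 (3 when adjusted over the list alone), with a median of 1.07. Their list call at the preset correlation (adjusted p = 0.00107) was lost with adjusted p = 0.451 with an estimated correlation. Mmp9 lost its call without any 1 of 3 Ezh2-null libraries, batch 1 replicate 1 and batch 2 replicates 1 and 3 (edgeR adjusted p up to 0.107). Mmp8 had 2 counts over the Ezh2-null and 2716 over the JAK2-VF Ezh2-null libraries, a ratio of 826 (exact interval 228 to 6830, counting error only). Hbb-bt rose by 3.24 ± 0.54 on the log2 scale (edgeR adjusted p = 0.000276), above every Ezh2-null library in 6 of 6. The other genes given here with a log2 change lay beyond every Ezh2-null library, in the direction given, in 6 of 6.

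Within batch 1 alone 3 genes passed and within batch 2 alone 373, in females alone 56, with the replicate number as a block 421 and in a fit of the compared groups alone 252, while DESeq2 called 1117. Without Ezh2-null batch 2 replicate 1 or replicate 3 the counts were 357 and 450.

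The JAK2-VF effects with and without Ezh2 share no library, but they share the terms for batch and sex of a single fit. In both, 167 genes rose, where 10.3 would be expected of independent lists, and 82 fell, where 5.39 would be expected (Fisher's exact test, one-sided p = 8.4e-170 and 7.81e-76). That test treats genes as independent, although genes such as those of proliferation move together. Its p-values measure no spread between libraries. The log2 changes had a Pearson correlation of 0.585 and a Spearman correlation of 0.51 across the 10183 genes with a mean log2 CPM of at least 3, which are not independent replicates. Only Lgals1, the gene of the secreted lectin galectin-1, passed in opposite directions, at -0.84 ± 0.22 with Ezh2 and 1.10 ± 0.23 without it on the log2 scale (edgeR adjusted p = 0.0243 and 0.00268; beyond every library of the other group in 4 of 6 and 6 of 6).

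JAK2-VF Ezh2-null stem cells compared with control cells joined these shifts. Of 52 proliferation genes 41 rose and 0 fell, of 50 interferon-stimulated genes 14 rose and 0 fell, and of 45 HSC signature genes 18 fell and only Ifitm1 rose (49, 25, and 25 with 3 when adjusted over each list alone). The proliferation and HSC lists each gave adjusted p = 0.024 with an estimated correlation, whereas the interferon list was lost, with adjusted p = 0.0606. Socs2 went from 41.08 ± 13.3 CPM in controls (n = 4) to 228.5 ± 67.9 (n = 6), a log2 change of 2.46 ± 0.24 (edgeR adjusted p = 8.61e-08). The RNA of Hba-a1, an alpha-globin gene counted identically to its copy Hba-a2, was at 28.58 ± 32.9 CPM in controls, with a wide spread, and at 0.149 ± 0.13 in JAK2-VF Ezh2-null cells (edgeR adjusted p = 0.00246), while Hbb-bt rose from 30.05 ± 20 to 234.3 ± 110 CPM (edgeR adjusted p = 0.000357).

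In all, 819 genes changed, 469 higher and 350 lower. Gbp3 rose by 1.30 ± 0.17, Gbp7 by 0.95 ± 0.12 and Ifi27 by 1.28 ± 0.18 on the log2 scale, with edgeR adjusted p of at most 3.26e-05. The aldo-keto reductase gene Akr1c12 rose from 1.79 ± 0.482 to 21.66 ± 7.64 CPM (edgeR adjusted p = 4.43e-06), and the sialomucin gene Podxl rose by 3.05 ± 0.51 (edgeR adjusted p = 0.000234). Rhag, the erythroid ammonium transporter gene, rose by 2.07 ± 0.33 (edgeR adjusted p = 0.000116). Cdkn1b, the gene of the cell-cycle inhibitor p27, fell by 0.66 ± 0.14 (edgeR adjusted p = 0.00335). Igf2, with 585 counts in controls, was at least 431-fold lower against a floor of 3 counts over the group. The genes given here with a log2 change lay beyond every control in 6 of 6 libraries. Within batch 1 alone 118 genes passed and within batch 2 alone 111, the count was 400 without control batch 1 replicate 1, and DESeq2 called 1211.

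**Figure D4:**
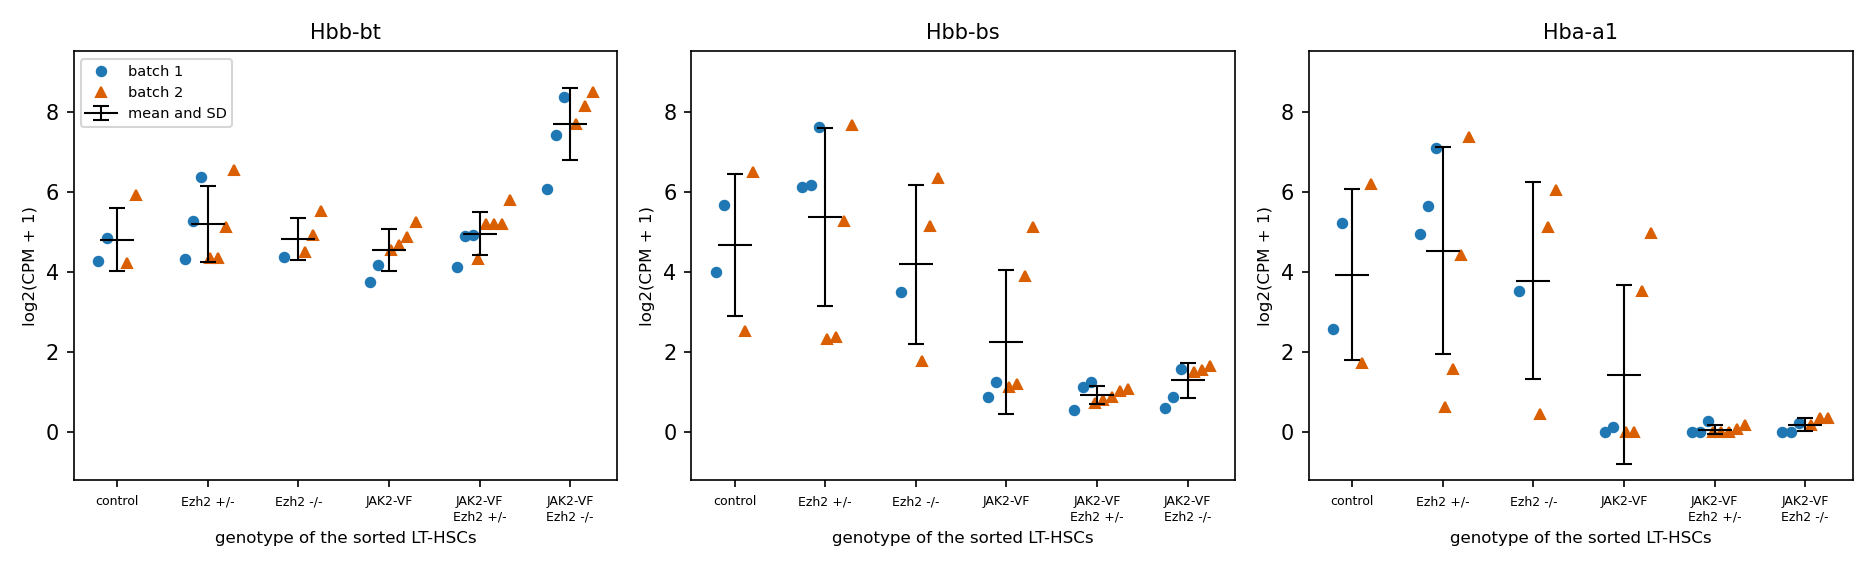
Level of Hbb-bt, of Hbb-bs and of Hba-a1 (y axis, log2(CPM + 1)) for each library, by genotype group (x axis), with circles for batch 1, triangles for batch 2 and the mean and SD on that scale. Hbb-bt averaged 234.3 CPM in JAK2-VF Ezh2-null libraries, whereas Hba-a1 averaged 0.149 CPM in the same libraries and 28.58 in controls.

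Between libraries labelled as having lost 1 Ezh2 allele and those with both, no gene passed the threshold, with or without JAK2-VF. Against control (n = 4), the libraries labelled Ezh2-heterozygous (n = 7) held 22.54 ± 9.66 against 8.92 ± 4.73 CPM of the liprin gene Ppfibp1, which did not pass the threshold (edgeR adjusted p = 0.538). Against JAK2-VF (n = 6), libraries labelled JAK2-VF Ezh2-heterozygous (n = 8) held 10.71 ± 6.58 against 3.35 ± 2.03 CPM of Dmwd and 36.78 ± 6.85 against 58.57 ± 8.85 CPM of Fam98a, again without passing (edgeR adjusted p = 0.833 and 1).

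Without JAK2-VF, edgeR called 0 genes and 772 had an unadjusted p under 0.05, against 747 expected by chance; DESeq2 called 64. With JAK2-VF, edgeR called 0, with 578 at an unadjusted p under 0.05, and DESeq2 called 44. With JAK2-VF, HSC signature genes had a median log2 value of 0.13 (35 of 45 positive) and proliferation genes -0.28 (2 of 52 positive), with 0 called in each by edgeR and 0 when adjusted over the list alone. Both lists were called at the preset correlation (adjusted p = 2.15e-07 and 1.99e-08) and lost with an estimated correlation (adjusted p = 0.147 and 0.514). The mean log2 level of interferon-stimulated genes was 6.15 ± 0.13 in libraries labelled JAK2-VF Ezh2-heterozygous against 5.95 ± 0.13 in JAK2-VF libraries (exact two-sided permutation p = 0.0133, adjusted 0.0266), above every JAK2-VF library in 6 of 8. The list call at the preset correlation (adjusted p = 1.39e-05) was lost with adjusted p = 0.514 with an estimated correlation, and 0 of 50 genes were called by edgeR, 0 also when adjusted over the list alone. Without JAK2-VF it was 6.4 ± 0.28 against 6.24 ± 0.09 (exact permutation p = 0.297, adjusted 0.297). In these comparisons limma-voom called 0 genes, as did edgeR within each batch, except for 1 gene without JAK2-VF in batch 2 alone.

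The difference between the Ezh2-null effects with and without JAK2-VF was tested directly. Lgals1 (Entrez 16852) was the only gene to pass, at 29.82 ± 5.88 CPM in control, 25.27 ± 6.58 in Ezh2-null, 20.01 ± 5.24 in JAK2-VF and 45.3 ± 9.85 in JAK2-VF Ezh2-null cells, a log2 difference of effects of 1.94 ± 0.34 (edgeR adjusted p = 0.0277). Next among genes with a mean log2 CPM of at least 3 were Hbb-bt (3.75 ± 0.77), Ncam2 (3.10 ± 0.63) and Xbp1, a plasma-cell and stress-response transcription factor gene (1.30 ± 0.27), none past the threshold (edgeR adjusted p = 0.0775 each). For interferon-stimulated genes the median difference of effects was 0.22, positive for 37 of 50, with 0 called by edgeR and 0 when adjusted over the list alone. The list call at the preset correlation (adjusted p = 0.00874) was lost with adjusted p = 0.739 with an estimated correlation. A larger interferon shift with JAK2-VF was thus not shown. For the immediate-early and dissociation stress genes the median difference of effects was -0.91, positive for 2 of 29, with 0 called by edgeR and 0 when adjusted over the list alone. Their list call at the preset correlation (adjusted p = 1.6e-12) was lost with adjusted p = 0.358 with an estimated correlation.

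Lgals1 lost its call without any 1 of 7 of the 20 libraries (control batch 1 replicate 1 and batch 2 replicate 4, Ezh2-null batch 2 replicates 1 and 3, JAK2-VF batch 1 replicate 1, and JAK2-VF Ezh2-null batch 2 replicates 1 and 2; edgeR adjusted p up to 0.118). No gene passed within either batch, limma-voom gave the same single count, DESeq2 called 92, and 9 genes passed without JAK2-VF Ezh2-null batch 1 replicate 2. The difference between the heterozygous effects gave 0 genes by edgeR (622 at an unadjusted p under 0.05) and 56 by DESeq2. Its smallest p-values among genes with a mean log2 CPM of at least 3 included that of Ppfibp1 (log2 -1.81 ± 0.45), which did not pass (edgeR adjusted p = 0.967).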

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

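The tests on the library labelled Ezh2-heterozygous batch 1 replicate 3 were chosen after the result was seen. Of 225 sets of values within a group, 18 held a library far from the others, where about 11 would be expected by chance, and JAK2-VF Ezh2-null batch 1 replicate 2 held 5 of them. That library was low for Cox4i2 (32.5 CPM), Ifitm1 (730 CPM) and Socs2 (110 CPM), and high for the MHC class II genes H2-Aa (330 CPM) and H2-Ab1 (241 CPM). JAK2-VF batch 1 replicate 1 was low for Cbx6 (96.8 CPM), Runx1t1 (1.62 CPM) and Zbp1 (4.87 CPM). JAK2-VF batch 2 replicate 2 was the only library of its group with Lin28b counts (0.0618 CPM). Ezh2-null batch 2 replicate 2 was high for the exon part of Ezh2 (a share of 0.478%) and for the mean log2 level of erythroid genes (4.19), and was alone in its group with Mmp8 counts (0.0613 CPM). Low values were also found for Osm in Ezh2-null batch 2 replicate 1 (0.234 CPM), Pim2 in Ezh2-null batch 1 replicate 1 (68.9 CPM), Xbp1 in Ezh2-null batch 2 replicate 3 (119 CPM), Rhag in JAK2-VF Ezh2-null batch 2 replicate 2 (75.8 CPM) and Jak2 in control batch 2 replicate 2 (45.2 CPM). The library labelled Ezh2-heterozygous batch 2 replicate 2 had the highest mean log2 level of HSC signature genes in its group (7.6).

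Lgals1 was flagged for a difference between the effects of Ezh2 loss with and without JAK2-VF, of 1.94 ± 0.34 on the log2 scale (edgeR adjusted p = 0.0277), the only one past the threshold. Its call was lost without any 1 of 7 of the 20 libraries, without a term for sex (edgeR adjusted p = 0.212), with the replicate block (0.14), in a fit of the compared groups (0.463), in either batch or females alone and without the 2 doubted libraries. Chance was not excluded, since 6 of 100 splits of the libraries gave as many genes.

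The library labelled Ezh2-heterozygous batch 1 replicate 3 had no count in the exon part of Ezh2. Too few counts are argued against: at the lowest share of the other libraries of the group, 1.738%, the chance of 0 in 831 counts is 4.7e-07. That chance covers counting error only, because the reads carry no molecular identifiers, and the share itself rests on 13 of 748 counts. A wrong label, or loss of the second allele in these cells, may account for it. The mean log2 level of interferon-stimulated genes in this library was 6.84, within the 6.45 to 6.98 of the Ezh2-null libraries and above the 5.99 to 6.63 of the other libraries labelled Ezh2-heterozygous, but the ranges of these groups overlap. Its whole-gene Ezh2 level, 44.7 CPM, lay above the 19.2 to 28.4 CPM of the Ezh2-null libraries and within the 24.9 to 50.4 CPM of the other libraries labelled Ezh2-heterozygous. Coro2a, the single gene called for Ezh2 loss without JAK2-VF, was at 169 CPM, against 52.3 to 121 CPM in Ezh2-null and 100 to 177 CPM in the other libraries labelled Ezh2-heterozygous. The interferon level therefore goes with a wrong label and the other 2 values with the label as given. The ranges of the Ezh2-null libraries are weak references, because only 1 of the 4 was from batch 1, as this library was. That Ezh2-null library had the highest whole-gene Ezh2 level of the 4, 28.4 CPM, and the lowest Coro2a level, 52.3 CPM. A wrong label stays open, and a biological loss of the second allele was not tested.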

How the results depend on the processing

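The fit without the 2 doubted libraries, those labelled Ezh2-heterozygous batch 1 replicates 1 and 3, was chosen after the data were seen. For Ezh2-null against control, edgeR with DESeq2 size factors, without a low-count filter, with the replicate block, in batch 1, batch 2 or females alone, or without the doubted libraries gave 0 genes, as did limma-voom, while DESeq2 gave 97. For the heterozygous effect DESeq2 gave 64 genes without JAK2-VF and 44 with it, and the block and batch 2 alone each gave 1 without JAK2-VF. For JAK2-VF against control DESeq2 gave 1003, batch 1 alone 83, batch 2 alone 38 and females 411. For JAK2-VF Ezh2-null against JAK2-VF, DESeq2 gave 193, limma-voom 107, the compared groups 22, batch 1 alone 1, batch 2 alone 22 and females 8. For JAK2-VF Ezh2-null against Ezh2-null, DESeq2 gave 1117, the block 421, the compared groups 252, batch 1 alone 3, batch 2 alone 373 and females 56. For JAK2-VF Ezh2-null against control, batch 1 alone gave 118 and batch 2 alone 111. The difference of Ezh2-null effects gave 92 genes with DESeq2, 2 without a term for sex, and 0 with the block, the compared groups, either batch, females or without the doubted libraries, and the difference of heterozygous effects 56 with DESeq2. The overlap of Ezh2-null calls was 6 with DESeq2. Leaving out 1 library gave 0 to 2 genes for Ezh2-null, 282 to 676 for JAK2-VF, 38 to 66 for Ezh2 loss with JAK2-VF, 357 to 668 for JAK2-VF in Ezh2-null cells, 400 to 760 for JAK2-VF Ezh2-null against control and 0 to 9 for the difference of Ezh2-null effects. Fits on fewer libraries have less power, and the cause of the other shifts was not tested. Of 207 named calls, 205 held with DESeq2 size factors, 203 with DESeq2, 185 with limma-voom, 184 without a low-count filter, 188 without a term for sex, 163 with the block, 202 without the doubted libraries, 95 in females, 90 in batch 2 and 36 in batch 1, and of the 201 with a value in a fit of the compared groups 110 held. With an estimated correlation, 0 lists shifted for Ezh2-null, for either heterozygous effect and for either difference of effects, as with fry, 2 for Ezh2 loss with JAK2-VF (2 with fry), 2 for JAK2-VF in Ezh2-null cells (9 with fry) and 3 for JAK2-VF Ezh2-null against control (7 with fry). Log2 values changed sign for Ezh1 in Ezh2-null cells (-0.15 with the block, -0.49 in batch 1), Jak2 in libraries labelled heterozygous (0.29 in batch 1, 0.01 in females) and, in JAK2-VF Ezh2-null against Ezh2-null, Ezh2 (-0.05 in batch 1, -0.17 in females), Rarb (0.71), Phf1 (0.30) and Kit (0.09) in batch 1 and Pdgfra (1.85) in females. So did the difference of Ezh2-null effects for Ezh1 (0.03 with limma-voom, 0.32 with the block, 0.04 in the compared groups, 0.54 in batch 1, 0.02 in females), and that of heterozygous effects for Ezh1 (0.07 with limma-voom, 0.22 with the block, 0.05 in batch 1, 0.16 in females, 0.06 without the doubted libraries) and Jak2 (-0.03 in batch 1). With 1 library left out, values around 0 ran from -0.23 to 0.13 for Jak2 in Ezh2-null cells, -0.15 to 0.14 for Jak2 in libraries labelled heterozygous, -0.13 to 0.08 and -0.08 to 0.10 for the 2 differences for Ezh1 and -0.08 to 0.22 for that of heterozygous effects for Jak2. Replicate numbers did not pair the libraries: over 69 pairs with the same number the mean correlation was -0.029, 6 exceeded 0.1, and 13 of 34 libraries matched best with their own number. What could be called was limited in the smallest groups, of 4 libraries, with 32.7% of 2-fold changes above 8 CPM recovered in simulated data for Ezh2-null against control. The effect of depth was not tested.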

Other observations

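The tests on globins and on interferon-stimulated genes were chosen after the results were seen, and the counts over other splits of the libraries were planned. In JAK2-VF against control cells 1 of 11 PRC2 genes and 2 of 19 PRC1 genes were called, all lower (2 higher and 1 lower, and 1 higher and 3 lower, when adjusted over each list alone), and neither list was called (adjusted p = 0.739 and 0.631 with an estimated correlation). Ezh1, the other catalytic subunit of PRC2, fell from 109.6 ± 8.19 to 74.52 ± 18.7 CPM (edgeR adjusted p = 0.0407), and it fell in JAK2-VF Ezh2-null against Ezh2-null cells as well, by 0.63 ± 0.18 on the log2 scale (edgeR adjusted p = 0.0295). Cbx7 and Cbx6, chromodomain subunits of PRC1, fell by 0.84 ± 0.22 and 0.48 ± 0.14 with JAK2-VF (edgeR adjusted p = 0.0259 and 0.0377). Each of the 3 lay below every control in 6 of 6 libraries. Their calls against control did not hold with single libraries left out: Ezh1 lost it without any 1 of 8 of 10 libraries, Cbx6 without any 1 of 5 and Cbx7 without any 1 of 3, with edgeR adjusted p up to 0.137, 0.171 and 0.112. The call of Ezh1 in cells without Ezh2 was lost without any 1 of 5 libraries (edgeR adjusted p up to 0.0975). Of 33 mitochondrial electron transport genes, 31 had positive log2 values with JAK2-VF and a median of 0.24, with 1 called (2 when adjusted over the list alone). Their list call at the preset correlation (adjusted p = 5.38e-06) was lost with adjusted p = 0.384 with an estimated correlation.

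Markers of mature cells varied widely within groups. The neutrophil granule gene Ngp ran from 4.84 to 5225 CPM over all libraries, and the mean log2 level of neutrophil and monocyte genes was 4.81 ± 0.319 in control and 4.23 ± 0.626 in Ezh2-null libraries. Lin28b, which had 2 counts in JAK2-VF and 1262 in JAK2-VF Ezh2-null libraries, had 43 in control, 170 in Ezh2-null, 154 in libraries labelled Ezh2-heterozygous and 0 in those labelled JAK2-VF Ezh2-heterozygous.

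Hbb-bt and its identical copy Hbb-b2 rose in JAK2-VF Ezh2-null cells. RNA from red cells is argued against, because Hba-a1 in these 6 libraries reached at most 0.268% of the level that its ratio to Hbb-bt in controls, 0.948, would give. Reads shared with other beta-globin copies are argued against too, because the 5 other copies together reached at most 4.65 CPM, or 1.97% of the mean of Hbb-bt. A strain or haplotype variant at the beta-globin locus was not tested and may account for the rise. Ezh2 loss without JAK2-VF went with no rise, at 30.05 ± 20 CPM in control and 29.21 ± 13 in Ezh2-null cells (log2 -0.29 ± 0.54, edgeR adjusted p = 1), and the difference of effects missed the threshold (3.75 ± 0.77, edgeR adjusted p = 0.0775), so an effect of Ezh2 loss that needs JAK2-VF was not shown and stays open.

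Interferon-stimulated genes were higher in JAK2-VF Ezh2-null than in JAK2-VF cells. A batch difference is argued against, because both groups held libraries of both batches and the mean log2 level differed by 0.81 in batch 1 and 0.71 in batch 2. The groups were fully separated over all libraries, so their separation within each batch follows from that and adds no support. RNA from neutrophils and monocytes was tested in several forms, all after the result was seen. Adjusted for batch and sex, their level by itself did not decide, with a difference of -0.11 ± 0.49, and as a covariate it left an interferon difference of 0.71, but within groups the interferon level had a slope of -0.01 ± 0.05 on it, which with 2 standard errors added to slope and difference gives a rise of at most 0.07 against an interferon difference of 0.71 ± 0.12 adjusted in the same way. An effect of Ezh2 loss may remain as a hypothesis, and differences in cell handling, housing, infection or litter, which no label gives, were not tested.

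Counts over other splits of the same libraries put the real split first in 4 comparisons, which by itself does not exclude chance. The other splits ignored batch and sex. They also moved real group differences into the spread shared by all groups, which lowers their numbers of calls. In 100 splits, the real one included, only the real split gave as many genes: 631 for JAK2-VF against control (highest other 3), 71 for JAK2-VF Ezh2-null against JAK2-VF (14), 723 for JAK2-VF Ezh2-null against Ezh2-null (19) and 819 for JAK2-VF Ezh2-null against control (78). The real split did not stand alone for the single gene of Ezh2-null against control, since 4 of 35 splits gave as many (highest other 1). The same held for the single gene of the difference of Ezh2-null effects, with 6 of 100 (highest other 2). Chance was not excluded for either. With 0 genes called any split gives as many, so all 100 did, and the splits say nothing about chance for heterozygous against control (highest other 11), for JAK2-VF heterozygous against JAK2-VF (1) and for the difference of heterozygous effects (3).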
